A study of Homo sapiens with 16 samples.

How the data were processed

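RNA sequencing was carried out on 22Rv1 cells, a human prostate cancer line that models castration-resistant disease, which grows although androgen is withheld. Each of 3 lines carried a short hairpin RNA (shRNA) that is made only when doxycycline (Dox) is added. The hairpin targeted PRMT5, an arginine methyltransferase, in the shPRMT5 line. It targeted WDR77, the gene of the PRMT5 partner MEP50, in the shMEP50 line, and CLNS1A, the gene of the PRMT5 adaptor pICln, in the shpICln line. Per the labels' protocols, Dox was given at 1 µg/mL every 48 h, total RNA was taken with Trizol, and libraries were made with the NEBNext Ultra II kit. The number of days on Dox is not given in the sources used here. The 16 libraries formed 6 groups, with and without Dox in each line. There were 2 libraries per group in shPRMT5 (replicates 2 and 3) and 3 libraries per group in shMEP50 and shpICln. Replicate 1 of shPRMT5 and a non-targeting hairpin with Dox were not analysed here. Per the labels, libraries of a group are biological replicates.

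The authors deposited raw read counts for 134648 transcripts with transcript length and exon coordinates on hg38, per the file headers. The deposited table also gives log2 RPKM values (read counts scaled to transcript length and library size) for each library. It also holds the log2 fold change, p-value and adjusted p-value of the authors' own Dox comparison in each line. Per the submitters' processing notes, the tools were FastQC, MultiQC, STAR, SAMtools, featureCounts and edgeR. Their roles, versions and settings, and whether counting used the strand, are not given in the sources used here. All 134648 transcripts matched an identifier in GENCODE 29, and 98.4% had the same start and end there. No transcript had fewer than 43 counts over the 16 libraries, so genes of very low expression are missing from every test. The table counts a read in each transcript in which it lies. Column totals of 111258497 to 159478067 counts were therefore 4.77 to 5.03 times the sum over genes of the most-counted transcript. That sum was 23305765 to 31826082 and is nearer to the number of reads assigned. Read duplicates were not marked in the table, so precision is judged from the spread between replicates.

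Counts were summed per gene name, which gave 23334 genes. Among these names, 84 covered more than 1 gene identifier. Genes were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test, with TMM normalization, a term for each of the 6 groups and no further covariate. All 16 libraries entered 1 fit and shared its estimate of the spread. The expression filter of edgeR removed 0 of the 23334 genes. P-values were adjusted over all genes by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Adjusted p-values of single genes in the text are from this fit unless another is named. The difference in Dox effect between 2 lines was tested as an interaction contrast in the same fit. CPM in the text are counts scaled to library size with TMM factors, given as mean ± SD. The median log2 fold change over all genes was 0.01 in shPRMT5, 0.01 in shMEP50 and -0.02 in shpICln.

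Before the data were examined, 36 gene lists of pathways, protein complexes and cell types were fixed, with 966 entries, of which 910 were found in the table. Lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, and p-values were adjusted over 108 tests, 36 lists in 3 lines. Camera was also run with the correlation estimated from the data, and fry was run beside it. The genes named in the text follow a rule fixed at the same time. It takes the target of each hairpin and, per line, the 10 largest rises and 10 largest falls among called protein-coding genes with a mean log2 CPM of at least 1 whose Dox libraries all lay beyond all libraries without Dox. It adds up to 4 called members with the smallest p per list and line, genes called in all 3 lines (up to 10), the 5 genes with the smallest p per difference between lines, and KLK3 and CDKN1A in each line. Some genes that the rule takes are not reported here. Genes named outside this rule were chosen after their values were seen, and the text says so.

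Replicate numbers come from the labels. Whether a number pairs a library with Dox and one without was checked by correlating their deviations from the group means. Such deviations cancel out within a group, so a positive value for a pair brings lower values with other numbers. In shMEP50 the 3 pairs had r of 0.58, 0.37 and 0.51, and the highest r with another number was -0.25, -0.01 and -0.01. In shpICln the 3 pairs had r of 0.44, 0.22 and 0.24, against -0.22, 0.13 and 0.13. The numbers were therefore taken to pair the libraries in these lines, and the result of a fit with the replicate number as a block is printed where it changes a call or moves a count by more than 1.5 times. The fit without the block is the main one because it was chosen before the data were examined.

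The alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, RLE normalization, no expression filter, a filter of at least 1 CPM in at least 8 libraries, each line fitted alone, the replicate block, a test against a fold change of 1.5, transcripts without summing, and leaving out each library in turn. Others were chosen after seeing the data. They are the most-counted transcript of each gene, a correction of each library for GC content and transcript length (splines with 4 degrees of freedom, with and without the block), and leaving out genes with particular short sequences in the 3' untranslated region (UTR). The closing section gives their effect.

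The gene test was checked on simulated counts with 200 changed genes among 23224. The changed genes were drawn from those with a mean count of at least 100, and libraries were simulated without pairing by replicate number. For shPRMT5 the test made 107 calls, of which 5.61% were false, and it recovered 5.97%, 52.2% and 93.9% of genes changed by 0.5, 1 and 2 on the log2 scale. For shMEP50 it made 108 calls with 2.78% false and recovered 5.97%, 52.2% and 100%. For shpICln it made 111 calls with 4.5% false and recovered 4.48%, 67.2% and 87.9%. The camera step found 3 of 3 changed lists and 0 of 37 unchanged ones in simulated data of 5000 genes for shMEP50. These genes were drawn independently, so the check does not cover lists whose genes vary together. In the real data the estimated correlation in shMEP50 was 0.58 for S phase genes and 0.59 for mitosis genes. Tables were prepared with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures with matplotlib 3.10.9.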

Results

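Gene expression was measured in 22Rv1 cells with and without knockdown of PRMT5, of its partner MEP50 (gene WDR77) or of its adaptor pICln (gene CLNS1A). PRMT5 adds symmetric dimethyl groups to arginines of histones, Sm proteins and other substrates. MEP50 forms the core methyltransferase complex with it, and pICln brings Sm proteins to that complex. The 16 libraries comprised 2 with and 2 without Dox in shPRMT5, and 3 with and 3 without Dox in shMEP50 and in shpICln. Summed over each gene's most-counted transcript, depth was 23305765 to 31826082 counts per library. Correlations of log expression between libraries lay between 0.9411 and 0.9919. The first principal component held 43.4% of the variance and set shMEP50 apart from the other lines, with scores of -90.2 to -34.9 for shMEP50, -8.8 to 44.7 for shPRMT5 and 35.3 to 77.3 for shpICln. The question was which genes change when each of the 3 proteins is depleted, and whether the changes are shared.

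Each targeted transcript was lower with Dox in its own line. PRMT5 (ENSG00000100462, chromosome 14, 22920511 to 22929585 on hg38, minus strand) went from 332 ± 33.9 to 44.6 ± 7.04 CPM in shPRMT5 (n = 2 per group, log2 fold change -2.90, SE 0.328, edgeR quasi-likelihood adjusted p = 0.0034). WDR77 (ENSG00000116455, chromosome 1, 111439890 to 111449376, minus strand) went from 26.9 ± 3.89 to 6.76 ± 0.477 CPM in shMEP50 (n = 3 per group, log2 fold change -1.99, SE 0.14, edgeR adjusted p = 2.54e-06). CLNS1A (ENSG00000074201, chromosome 11, 77514936 to 77637805, minus strand) went from 123 ± 15.2 to 51.3 ± 18.3 CPM in shpICln (n = 3 per group, log2 fold change -1.26, SE 0.221, edgeR adjusted p = 0.0197). In each case every Dox library lay below every library without Dox. WDR77 also differed in shpICln, from 22.3 ± 2.76 to 15.6 ± 1.55 CPM (log2 fold change -0.52, SE 0.135), with an edgeR adjusted p of 0.0831, and of 0.00814 with the replicate block. PRMT5 had log2 fold changes of -0.42 (edgeR adjusted p = 0.456) in shMEP50 and -0.15 (edgeR adjusted p = 0.83) in shpICln. CLNS1A had log2 fold changes of 0.11 in shPRMT5 and 0.12 in shMEP50 (edgeR adjusted p = 0.856 and 0.865), and WDR77 had -0.13 in shPRMT5 (edgeR adjusted p = 0.698). The edgeR adjusted p of PRMT5 in shPRMT5 was 0.0528 without replicate 2 without Dox and 0.0623 without replicate 2 with Dox, at log2 fold changes of -2.79 and -2.75. That of CLNS1A in shpICln was 0.071 without replicate 2 without Dox, 0.083 without replicate 2 with Dox and 0.0693 without replicate 3 without Dox, at log2 fold changes of -1.22, -1.35 and -1.2. It was 0.0559 with the shpICln line fitted alone and 0.744 in a test against a fold of 1.5, both at -1.26.

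**Figure D1:**
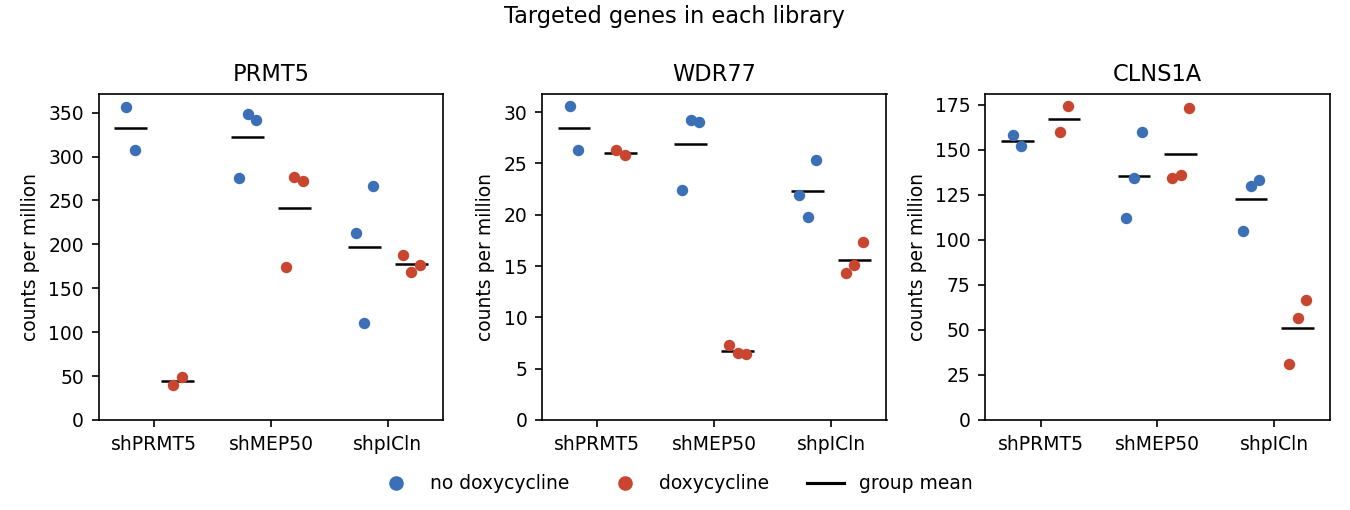
CPM (vertical axis, linear, from 0) of PRMT5, WDR77 and CLNS1A in each library of the 3 lines, with points for libraries without and with Dox and black lines for group means. In its own line each target lies lower in every Dox library than in any library without Dox, with means of 332 and 44.6 for PRMT5, 26.9 and 6.76 for WDR77, and 123 and 51.3 for CLNS1A.

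In shPRMT5, Dox lowered 13 of 49 genes of mitosis, 3 of 47 of S phase and 4 of 38 of homologous recombination, and raised 2 of 18 neuroendocrine markers. Their list tests and that of mitochondrially encoded transcripts passed camera at the preset correlation, and none of them with an estimated correlation (lowest adjusted p = 0.384). At an edgeR adjusted p under 0.05, 415 genes rose and 299 fell (714 of 23334), with 210 rising and 150 falling at least 2-fold. Among called genes with a mean log2 CPM of at least 1 and no overlap between the groups, the largest rise was in CX3CL1, a membrane-bound chemokine, from 0.678 ± 0.0654 to 4.45 ± 0.603 CPM (log2 fold change 2.71, SE 0.358, edgeR adjusted p = 0.00428). The proteoglycan gene SPOCK2 rose by 2.31 (SE 0.303, edgeR adjusted p = 0.00428), the adhesion molecule gene ICAM5 by 2.21 (SE 0.375, edgeR adjusted p = 0.0134) and the tubulin-binding gene TPPP3 by 2.19 (SE 0.292, edgeR adjusted p = 0.00428) on the log2 scale. The other large rises among such genes were MYEOV (log2 fold change 2.30), HBA2 (2.26), the kinase gene CDK18 (2.17), the ETS transcription factor gene ETV4 (2.11), the chromatin gene HMGA2 (2.02) and the chaperone gene HSPA2 (2.01), with edgeR adjusted p-values of 0.00364 to 0.0419. HBA2 has a near-identical copy, and its counts are uncertain. Beside PRMT5, the largest falls among such genes were in the zinc finger gene ZBTB7C (log2 fold change -2.86, SE 0.641, edgeR adjusted p = 0.0331) and the mitotic kinesin gene KIF20B (-2.45, SE 0.351, edgeR adjusted p = 0.00821). SLC22A10 (-2.16), the bicarbonate transporter gene SLC4A4 (-2.13), NAV3 (-2.11), RIPOR2 (-2.02), the interleukin receptor subunit gene IL1RAP (-2), the efflux transporter gene ABCC4 (-1.93) and the epithelial transcription factor gene EHF (-1.86, from 142 ± 4.8 to 39.1 ± 5.29 CPM) also fell, with edgeR adjusted p-values of 0.01 to 0.0492.

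The mitosis list had the smallest p in this line. Of 49 genes of G2/M and mitosis, 13 fell, 0 rose and 36 were not called, and 28 fell adjusted over the list alone (median log2 fold change -0.60, camera adjusted p = 7.9e-19, and adjusted p = 0.537 with an estimated correlation). CDK1, the kinase that drives entry into mitosis, went from 173 ± 33.2 to 83.9 ± 12.8 CPM (log2 fold change -1.04, edgeR adjusted p = 0.011), and DLGAP5 (-1.28), HMMR (-1.33) and CCNB1 (-0.80) fell too. Of 47 genes of DNA replication and S phase, 3 fell, 0 rose and 44 were not called, and 14 fell adjusted over the list alone (median -0.35, camera adjusted p = 5.37e-08, and adjusted p = 0.795 with an estimated correlation). The replication gene GINS1 (-1.02) and the helicase gene MCM2 (-0.96) were among them. Of 38 homologous recombination genes, 4 fell, 0 rose and 34 were not called, and 6 fell adjusted over the list alone (median -0.43, camera adjusted p = 3.29e-07, and adjusted p = 0.384 with an estimated correlation). BRCA2, which acts in repair of broken DNA, fell from 10.6 ± 1.74 to 3.98 ± 0.241 CPM (log2 fold change -1.41, edgeR adjusted p = 0.0266), beside MRE11 (-1.05), RMI1 (-1) and BARD1 (-0.98). Of 29 histone genes expressed in S phase, 1 fell, 0 rose and 28 were not called, also 1 adjusted over the list alone (HIST1H2BO, -2.33). The list median was -0.52 (camera adjusted p = 0.00224, and adjusted p = 0.869 with an estimated correlation), and histone genes share near-identical sequence, so their single values are uncertain.

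Neuroendocrine markers, genes of a cell type other than the luminal cells that 22Rv1 models, had the highest median. Of 18 such genes, 2 rose, 0 fell and 16 were not called, and 8 rose adjusted over the list alone (median log2 fold change 0.95, camera adjusted p = 1.38e-05, and adjusted p = 0.636 with an estimated correlation). ENO2, neuron-specific enolase, rose from 129 ± 14.2 to 311 ± 6.92 CPM (log2 fold change 1.27, edgeR adjusted p = 0.011), and RCOR2 rose by 1.36 on the log2 scale (edgeR adjusted p = 0.0496). Members outside the fixed rule, named after their values were seen, were CHGA (1.51), POU3F2 (1.42), PEG10 (1.2), SNAP25 (1.19), SYP (1.09) and BEX1 (0.98), called only over the list alone. Of 13 mitochondrially encoded protein genes, edgeR called 0, with 8 at an unadjusted p under 0.05, all higher. DESeq2 called 6, limma-voom 0, and 8 rose adjusted over the list alone (median 0.44, camera adjusted p = 5.62e-06, and adjusted p = 0.636 with an estimated correlation). Mitochondrial transcripts made up 6.74% and 6.79% of counts without Dox and 8.51% and 8.24% with Dox. Of 47 nuclear genes of oxidative phosphorylation, 2 rose (COX7A2 by 0.70 and NDUFA10 by 0.54 on the log2 scale), 0 fell and 45 were not called, and 8 rose adjusted over the list alone (median 0.31, camera adjusted p = 8.76e-06, and adjusted p = 0.869 with an estimated correlation).

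Further lists passed in shPRMT5 with few called members. Of 55 ribosomal protein genes, edgeR called 0, with 2 higher at an unadjusted p under 0.05, 0 by DESeq2, 0 by limma-voom and 0 adjusted over the list alone (median 0.26, camera adjusted p = 0.00305, and adjusted p = 0.904 with an estimated correlation). Of 18 androgen-repressed genes, DDC fell (log2 fold change -1.41), 0 rose and 17 were not called, and 2 fell adjusted over the list alone (median -0.48, camera adjusted p = 0.0287, and adjusted p = 0.508 with an estimated correlation). Of 16 fatty acid synthesis genes, FADS1 (-0.82) and PNPLA3 (-0.87) fell, 0 rose and 14 were not called, also 2 adjusted over the list alone (median -0.27, camera adjusted p = 0.0287, and adjusted p = 0.812 with an estimated correlation). Without a single shPRMT5 library these camera adjusted p-values moved past the threshold, to 0.0517 and 0.173 for the androgen-repressed and fatty acid lists without replicate 2 with Dox. They moved to 0.0601, 0.104 and, for ribosomal proteins, 0.0603 without replicate 3 without Dox. Ribosomal proteins also had 0.0691 without replicate 3 with Dox. The PRMT5 complex list had a median of 0.06 while its test pointed down (camera adjusted p = 0.186), and PRMT5 fell while the other 4 genes were not called. Without shpICln replicate 2 without Dox that list, which holds the target of the hairpin, had 0.0252. Without replicate 3 with Dox, p53 targets had 0.00747 and ribosome biogenesis and MYC targets 0.0131, and the latter had 0.0348 without replicate 3 without Dox, all pointing down. AKR1C3, an enzyme of androgen synthesis with close paralogs that makes its counts uncertain, rose by 1.92 on the log2 scale (edgeR adjusted p = 0.011), and RRM2B, SUV39H1 and BIRC5 fell by 0.98, 1.15 and 0.69. Other called list members were HERC3 (-1.56), BST2 (1.66), HSPA1A (1.21, uncertain because of its near-identical copy HSPA1B), IFI35 (0.98), LUC7L (0.50) and SMUG1 (0.46).

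The shPRMT5 calls depended on each of its own 4 libraries. Without them in turn edgeR called 0 genes (replicate 2 without Dox, with 2687 at an unadjusted p under 0.05), 6 (replicate 2 with Dox), 87 (replicate 3 without Dox) and 10 (replicate 3 with Dox), and 0 of the 52 named genes called in this line stayed called in all 16 such fits. Without shMEP50 replicate 1 without Dox the count was 1216, and without shMEP50 replicate 3 with Dox 1096. Without shpICln replicate 1 with Dox, replicate 2 with Dox, replicate 3 without Dox and replicate 3 with Dox it was 462, 371, 429 and 452. With this line fitted alone edgeR called 5290 genes, and 712 of the 714 stayed called. With all libraries DESeq2 called 2339 genes, and 4948 genes had an unadjusted edgeR p under 0.05. Markers of other cell types gave camera adjusted p-values of 0.415 for basal epithelium (median -0.19, 12 genes), 0.728 for fibroblasts (0.02, while the test pointed down, 21 genes) and 0.683 for blood and endothelium (0.05, 5 genes).

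In shMEP50, Dox lowered 29 of 47 genes of DNA replication and S phase, 15 of 49 of mitosis, 9 of 38 of homologous recombination and 4 of 18 of the Fanconi anaemia pathway, and raised 8 of 34 p53 targets. These lists passed camera at the preset correlation, and none of them with an estimated correlation (lowest adjusted p = 0.213). At an edgeR adjusted p under 0.05, 288 genes rose and 590 fell (878 of 23334), with 80 rising and 209 falling at least 2-fold. Among called genes with a mean log2 CPM of at least 1 and no overlap between the groups, the largest rise was in MSMB, a secreted protein of prostate epithelium, from 3.36 ± 2.42 to 29.6 ± 14.3 CPM (log2 fold change 3.14, SE 0.509, edgeR adjusted p = 0.00284). FAIM2, an inhibitor of Fas signalling, rose by 2.21 (SE 0.435, edgeR adjusted p = 0.00981) and PAPSS2, which makes the sulfate donor of the cell, by 2.11 (SE 0.314, edgeR adjusted p = 0.00148) on the log2 scale. The other large rises among such genes were CYP3A43 (log2 fold change 1.99), MFSD4A (1.96), S100A6 (1.89), PHGR1 (1.89), SDK1 (1.81), ST6GALNAC2 (1.74) and S100P (1.69, from 77.5 ± 29.7 to 250 ± 109 CPM), with edgeR adjusted p-values of 0.00325 to 0.0197. The largest falls among such genes were in the neonatal Fc receptor gene FCGRT (log2 fold change -2.45, SE 0.363, edgeR adjusted p = 0.00147), the secretory granule gene SCG3 (-2.40, SE 0.466, edgeR adjusted p = 0.00921) and ANAPC13, a subunit of the anaphase-promoting complex (-2.27, SE 0.17, edgeR adjusted p = 5.28e-06). The sorting nexin gene SNX12 fell from 41.4 ± 2.22 to 9.52 ± 0.793 CPM (-2.12, SE 0.0977, edgeR adjusted p = 3.34e-08), and H2AFZ, the gene of histone variant H2A.Z, from 509 ± 20.6 to 134 ± 24.9 CPM (-1.93, SE 0.122, edgeR adjusted p = 9.8e-07). H2AFZ overlaps the transcript AC097460.1, and whether counting used the strand is not stated. PON1 (-2.08), GPR85 (-1.91), EPB41L2 (-1.87) and SNTB1 (-1.87) also fell, with edgeR adjusted p-values of 0.000235 to 0.0449. GPR85 was not called in 13 of 16 fits without 1 library. Without replicate 1 without Dox SNTB1 had -1.02, and without replicate 1 with Dox MFSD4A had 1.3, and neither was called.

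Of 47 genes of DNA replication and S phase, 29 fell, 0 rose and 18 were not called, and 44 fell adjusted over the list alone (median log2 fold change -0.72, camera adjusted p = 1.51e-47, and adjusted p = 0.234 with an estimated correlation). GINS1 went from 17.2 ± 1.82 to 5.23 ± 0.81 CPM (log2 fold change -1.72, edgeR adjusted p = 1.59e-05). RFC3, part of the clamp loader, fell by 1.48, the S phase transcription factor gene E2F1 by 1.39 and TYMS, which makes thymidylate, by 0.68. Of 49 genes of G2/M and mitosis, 15 fell, 0 rose and 34 were not called, and 31 fell adjusted over the list alone (median -0.52, camera adjusted p = 1.12e-22, and adjusted p = 0.496 with an estimated correlation). CDK1 (-1.01), BIRC5 (-0.94), PTTG1 (-0.89) and MAD2L1 (-0.74) were among them. Of 38 homologous recombination genes, 9 fell, 0 rose and 29 were not called, and 22 fell adjusted over the list alone (median -0.41, camera adjusted p = 3.44e-12, and adjusted p = 0.213 with an estimated correlation). BRCA2 (-1.21), RAD51AP1 (-1.20) and RAD51D (-0.92) were among them. Of 18 Fanconi anaemia genes, 4 fell, 0 rose and 14 were not called, and 8 fell adjusted over the list alone (median -0.44, camera adjusted p = 3.07e-06, and adjusted p = 0.213 with an estimated correlation). These were FANCD2 (-1.03), FANCG (-0.98), FANCI (-0.71) and FANCA (-0.63). In these 4 lists 45, 35, 25 and 11 genes fell and 0 rose with the replicate block.

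Of 34 p53 targets, 8 rose, 0 fell and 26 were not called in shMEP50, and 17 rose and 1 fell adjusted over the list alone (median log2 fold change 0.45, camera adjusted p = 4.83e-12, and adjusted p = 0.468 with an estimated correlation). BTG2, an antiproliferative gene, rose from 10 ± 0.897 to 27.8 ± 7.41 CPM (log2 fold change 1.47, edgeR adjusted p = 0.00244), the mitophagy gene SPATA18 by 1.18, the proapoptotic gene BBC3 by 0.86 and the stress gene GADD45A by 0.66. CDKN1A, the cell cycle inhibitor p21, had a log2 fold change of 0.63 that was not called (edgeR adjusted p = 0.345, and 0.00293 with the replicate block). Its log2 fold changes were 0.06 in shPRMT5 and 0.12 in shpICln (edgeR adjusted p = 0.946 and 0.893). Of 41 genes of the integrated stress response, SESN2 (0.69) and SLC1A5 (0.48) rose and PSAT1 (-1.05) fell, 38 were not called, and 4 rose and 1 fell adjusted over the list alone (median 0.21, camera adjusted p = 0.00413, and adjusted p = 0.869 with an estimated correlation). Of 17 luminal epithelium genes, ELF3 (0.83) and TSPAN1 (0.88) rose, 0 fell and 15 were not called, and 6 rose adjusted over the list alone (median 0.21, camera adjusted p = 0.00515, and adjusted p = 0.384 with an estimated correlation). Of 25 cholesterol synthesis genes, MSMO1 rose by 0.75, 0 fell and 24 were not called, and 5 rose adjusted over the list alone (median 0.19, camera adjusted p = 0.00618, and adjusted p = 0.869 with an estimated correlation). With the replicate block 24 p53 targets rose and 2 fell, and 11 and 1 genes of the stress response, 6 and 1 of luminal epithelium and 6 and 0 of cholesterol synthesis. Without replicate 1 without Dox the stress response, cholesterol and luminal lists had camera adjusted p-values of 0.258, 0.0543 and 0.0744. The cholesterol list had 0.358 without replicate 1 with Dox and 0.0634 without replicate 2 without Dox.

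Splicing factors and genes with detained introns had a list test that pointed down in shMEP50. Of 38 genes, PTBP1 (log2 fold change -0.87, from 665 ± 24.1 to 365 ± 34.3 CPM), HNRNPDL (-0.64) and TRA2B (-0.38), which bind RNA in splicing, were called. In all, 3 fell, 0 rose and 35 were not called, also 3 adjusted over the list alone (median -0.10, camera adjusted p = 0.00305, and adjusted p = 0.696 with an estimated correlation). Of 5 genes of the PRMT5 complex and its adaptors, WDR77 fell, 0 rose and 4 were not called, also 1 adjusted over the list alone, with a median of 0.08 while the test pointed down (camera adjusted p = 0.00413, and adjusted p = 0.409 with an estimated correlation). WDR77 is the target of the hairpin, so this test is not evidence on the other members. Of 20 Sm protein and SMN complex genes, SNRPD2 fell by 1.32 on the log2 scale, and the list had a camera adjusted p of 0.132, and of 0.0412 with the replicate block. Genes of glycolysis and hypoxia had 0.0604 and 0.0412, and of the unfolded protein response 0.063 and 0.00987, with medians of -0.22 and -0.19. With the block and an estimated correlation these 3 lists had adjusted p = 0.843, 0.866 and 0.843, and 1 gene rose and 2 fell, 4 and 9, and 1 and 7. Without 1 shMEP50 library, replicate 1 without Dox, Sm proteins, glycolysis and the unfolded protein response had camera adjusted p-values of 0.0258, 0.000537 and 0.0116. Sm proteins also had 0.0016 and glycolysis 0.00977 without replicate 3 with Dox, and glycolysis and the unfolded protein response had 0.0461 and 0.0418 without replicate 1 with Dox. Left-out libraries of other lines gave glycolysis 0.0464 (shPRMT5 replicate 3 with Dox) and 0.047 (shpICln replicate 1 without Dox). They gave the unfolded protein response 0.0464 (shPRMT5 replicate 3 with Dox), 0.0245 and 0.0465 (shpICln replicate 3 without and with Dox). The list test of neuroendocrine markers pointed down (1 of 18 fell, SCG3, with 0 rising, 17 not called and 2 falling adjusted over the list alone, median -0.37, camera adjusted p = 0.025, and adjusted p = 0.869 with an estimated correlation). Without single shMEP50 libraries that list had camera adjusted p-values of 0.358 (replicate 1 without Dox), 0.273 (replicate 2 with Dox) and 0.0866 (replicate 3 without Dox). Of 55 ribosomal protein genes edgeR called 0, with 1 lower at an unadjusted p under 0.05, 0 by DESeq2, 0 by limma-voom and 0 adjusted over the list alone (median 0.16, camera adjusted p = 0.0157, and adjusted p = 0.904 with an estimated correlation). The direction of that test turned without replicate 1 without Dox (adjusted p = 0.712) and without replicate 3 with Dox (adjusted p = 0.656). In this line 3 splicing factors rose and 10 fell with the replicate block, as did 1 and 3 neuroendocrine markers and 15 and 1 ribosomal protein genes. Further lists passed without single shMEP50 libraries. Pointing down, fatty acid synthesis had 0.029 and 0.0337 without replicate 1 without and with Dox, and ribosome biogenesis and replication-dependent histones had 0.00967 and 0.00696 without replicate 1 without Dox. Pointing up, nuclear oxidative phosphorylation had 0.00457 without replicate 2 with Dox and 0.00207 without replicate 3 without Dox, and histone methylation and Polycomb genes had 0.0175 without replicate 3 with Dox.

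Single list members also changed in shMEP50. ACLY, which makes cytosolic acetyl-CoA, went from 429 ± 17 to 143 ± 28.2 CPM (log2 fold change -1.59, edgeR adjusted p = 8.51e-06). The glutathione synthesis gene GCLM (-1.17), the pentose phosphate gene PGD (-0.76), the interferon-induced genes MX1 (-1.15) and OAS3 (-0.94), CA12 (-1.33), HYOU1 (-0.96), BAG3 (-0.80), MAD2L2 (-0.72), GRWD1 (-0.71), FADS1 (-0.61), DIABLO (-0.57), NOP58 (-0.55), PARP2 (-0.51), DNAJA1 (-0.50), DNMT1 (-0.48) and NOLC1 (-0.36) fell. KRT14 (-1.83, from 0.286 to 0.0803 CPM) and HIST1H2AG (-1.76) fell at low expression. AKR1C3 (1.48), JARID2 (0.72), KDM6B (0.68), FTL (0.68) and the caspase gene CASP8 (0.65) rose. Fibroblast, basal and blood and endothelial markers gave camera adjusted p-values of 0.723 (median 0.01), 0.751 (0.09) and 0.313 (-0.62). With the replicate block edgeR called 1851 rises and 1870 falls (3721) in shMEP50, and DESeq2 called 1734 genes. With this line fitted alone edgeR called 48 genes, and 47 of the 878 stayed called. Leaving out any 1 library gave 628 to 928 calls, and 54 of the 80 named genes called in this line stayed called in all 16 such fits. The others were CITED2, NOLC1, SLC1A5, GPR85, DNMT1, GNMT, SESN2, JARID2, OAS3, FANCI, FTL, MSMO1, BAG3, TRA2B, KRT14, NOP58, FADS1, DIABLO, PARP2, SNTB1, MFSD4A, DNAJA1, GADD45A, CASP8, FANCA and KDM6B. OAS3 had -0.61 without replicate 1 without Dox.

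In shpICln, ribosomal protein genes and nuclear genes of oxidative phosphorylation had higher log2 fold changes than other genes by camera at the preset correlation, but not with an estimated correlation (adjusted p = 0.537 and 0.828). At an edgeR adjusted p under 0.05, 108 genes rose and 129 fell (237 of 23334), with 27 rising and 31 falling at least 2-fold. Among called genes with a mean log2 CPM of at least 1 and no overlap between the groups, the largest rise was in PDK4, a kinase that inhibits pyruvate dehydrogenase, from 3.27 ± 0.706 to 18.2 ± 5.7 CPM (log2 fold change 2.48, SE 0.468, edgeR adjusted p = 0.0253). SMOC1 rose by 1.99 (SE 0.423, edgeR adjusted p = 0.0398), the tyrosine kinase gene PTK6 by 1.95 (SE 0.333, edgeR adjusted p = 0.0188) and MAPK4 by 1.58 (SE 0.33, edgeR adjusted p = 0.0387) on the log2 scale. ASIC3 (1.33), the actin-binding gene TAGLN (1.22, edgeR adjusted p = 0.0028), BASP1 (1.19), CNKSR3 (1.19), the collagen gene COL7A1 (1.15) and LTO1 (1.11) also rose. DDR1, a collagen receptor kinase, fell from 1440 ± 180 to 395 ± 24.7 CPM (log2 fold change -1.87, SE 0.148, edgeR adjusted p = 6.21e-05), and CS, citrate synthase, from 747 ± 60.9 to 336 ± 13.9 CPM (-1.15, SE 0.144, edgeR adjusted p = 0.0045). SLITRK5 (-1.46), KIF20B (-1.27), ZIK1 (-1.27), GPRIN2 (-1.19), GNG12 (-1.11), TMX3 (-1.09) and CPNE1 (-1.07) completed the largest falls among such genes beside CLNS1A, with edgeR adjusted p-values of 0.00527 to 0.0425.

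Of 55 ribosomal protein genes, edgeR called 0 over all genes, with 48 higher and 0 lower at an unadjusted p under 0.05. DESeq2 called 15 and limma-voom 3, all higher, 45 rose adjusted over the list alone, and 55 rose with the replicate block (median log2 fold change 0.60, camera adjusted p = 8e-31, and adjusted p = 0.537 with an estimated correlation). Of 47 nuclear oxidative phosphorylation genes, NDUFB8 rose (log2 fold change 0.69), 0 fell and 46 were not called, and 2 rose adjusted over the list alone, while 24 rose and 1 fell with the replicate block (median 0.25, camera adjusted p = 2.35e-08, and adjusted p = 0.828 with an estimated correlation). Of 38 splicing factors and genes with detained introns, HNRNPA1 rose by 0.58 (from 1540 ± 177 to 2310 ± 137 CPM), 0 fell and 37 were not called, and 2 rose adjusted over the list alone (median 0.11, camera adjusted p = 0.00305, and adjusted p = 0.696 with an estimated correlation). Of 38 homologous recombination genes edgeR called 0, with 1 higher and 8 lower at an unadjusted p under 0.05, 1 lower by DESeq2, 0 by limma-voom and 0 adjusted over the list alone (median -0.12, camera adjusted p = 0.025, and adjusted p = 0.783 with an estimated correlation). Of 16 fatty acid synthesis genes edgeR called 0, with 5 lower at an unadjusted p under 0.05, 2 lower by DESeq2, 0 by limma-voom and 2 falling adjusted over the list alone (median -0.21, camera adjusted p = 0.0185, and adjusted p = 0.783 with an estimated correlation). Of 18 neuroendocrine markers edgeR called 0, with 3 higher at an unadjusted p under 0.05, 0 by DESeq2, 0 by limma-voom and 0 adjusted over the list alone (median 0.38, camera adjusted p = 0.0353, and adjusted p = 0.869 with an estimated correlation). With the replicate block 8 splicing factors rose and 0 fell, as did 1 and 10 homologous recombination genes, 0 and 4 fatty acid synthesis genes and 4 and 2 neuroendocrine markers. Without replicate 1 with Dox the splicing, fatty acid and neuroendocrine lists had camera adjusted p-values of 0.101, 0.0843 and 0.126, and homologous recombination had 0.175 without replicate 1 without Dox. Neuroendocrine markers also had 0.246 without replicate 2 without Dox, and they and fatty acid genes had 0.0647 and 0.202 without replicate 3 without Dox.

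The replicate block brought 3 more lists of shpICln past the threshold, androgen-repressed genes (median -0.37, camera adjusted p = 0.172, and 0.0325 with the block), G2/M and mitosis (-0.10, 0.0798 and 0.0407) and the integrated stress response (0.09, 0.0756 and 0.0336). With the block and an estimated correlation they had adjusted p = 0.449, 0.866 and 0.866, and 1 gene rose and 3 fell, 0 and 8, and 5 and 1. Other called list members were FOXM1 (log2 fold change -0.58), CASP8 (-0.71), ELF3 (0.77) and MT-ND4L (-0.45), which overlaps MT-ND4. The PRMT5 complex list was not called (median -0.15, camera adjusted p = 0.161). Without replicate 2 without Dox, G2/M and mitosis, the stress response and the PRMT5 complex had 2.92e-06, 3.04e-08 and 0.0315. Without replicate 1 with Dox, G2/M and mitosis and the stress response had 0.000521 and 0.0369, and androgen-repressed genes had 0.0457 without replicate 1 without Dox. Pointing up, Sm proteins had 0.00897 and 0.0349 without replicate 1 with Dox and replicate 3 without Dox, and ribosome biogenesis 0.014 and 0.0466 without replicates 2 and 3 without Dox. Pointing down, S phase genes had 0.0142 without replicate 2 without Dox, and histone genes 0.00525 and 0.0465 without replicate 1 without Dox and replicate 3 with Dox. Basal, fibroblast and blood and endothelial markers gave camera adjusted p-values of 0.907 (median 0.00), 0.78 (-0.12, while the test pointed up) and 0.896 (-0.10). With the replicate block edgeR called 1745 rises and 1901 falls (3646) in this line, and DESeq2 called 1053 genes. Without its own libraries in turn edgeR called 48 (replicate 1 without Dox), 30 (replicate 1 with Dox), 43 (replicate 2 without Dox), 26 (replicate 2 with Dox), 39 (replicate 3 without Dox) and 62 (replicate 3 with Dox) genes. Without those of shPRMT5 it called 118 and 106 (replicates 2 and 3 without Dox) and 113 and 114 (with Dox), and without shMEP50 replicate 3 with Dox 374. Of 29 named genes called in this line, 8 stayed called in all 16 such fits, namely TAGLN, CNKSR3, DDR1, CS, GNG12, CPNE1, AZGP1 and CITED2.

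**Figure D2:**
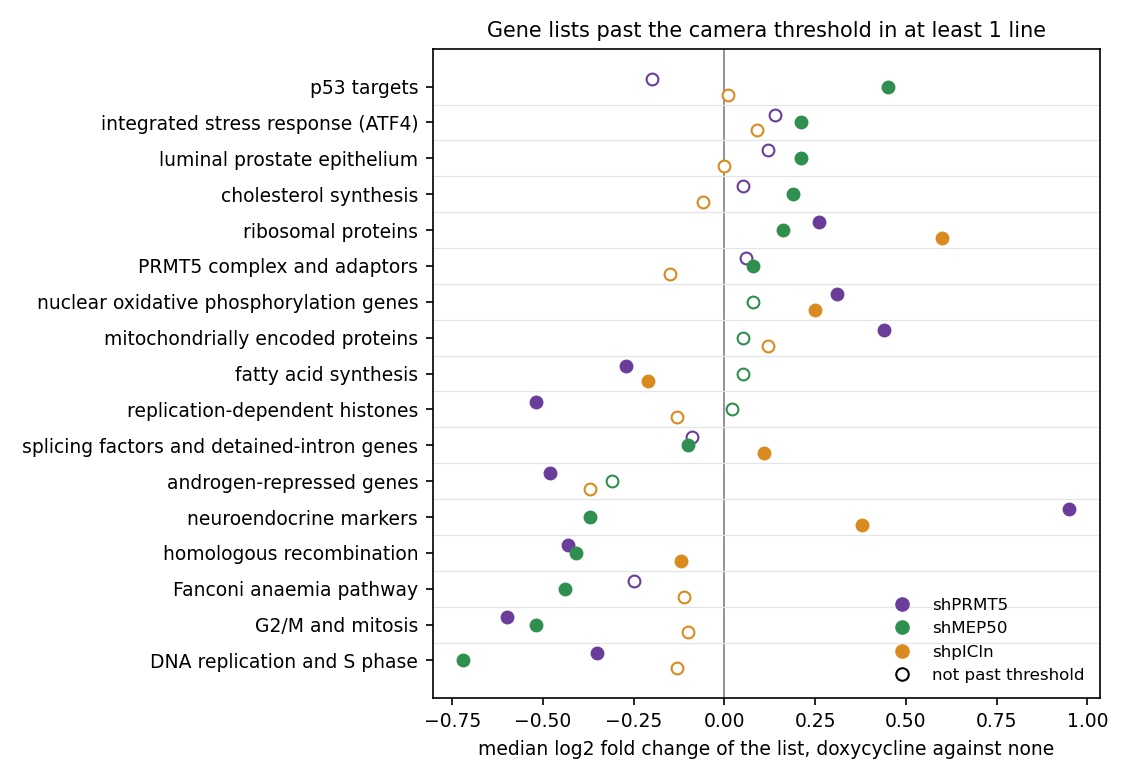
Median log2 fold change with Dox (horizontal axis) of each fixed gene list that passed the camera test at the preset correlation in at least 1 line. Colours give the line and filled points the lists past the threshold there, such as DNA replication and S phase at -0.72 in shMEP50, neuroendocrine markers at 0.95 in shPRMT5 and ribosomal proteins at 0.60 in shpICln.

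KLK3, the prostate-specific antigen gene, which androgen induces, went from 2260 ± 443 to 1240 ± 56 CPM in shPRMT5, from 3320 ± 1600 to 1900 ± 616 in shMEP50 and from 1050 ± 428 to 731 ± 247 in shpICln. Its log2 fold changes of -0.87, -0.81 and -0.52 were not called (edgeR adjusted p = 0.333, 0.349 and 0.581), and with the replicate block the adjusted p was 0.00173 in shMEP50 and 0.0171 in shpICln. Of 43 androgen-induced genes, 1 rose and 2 fell in shPRMT5, 2 rose in shMEP50 and 1 rose in shpICln, with camera adjusted p-values of 0.277, 0.447 and 0.708. Adjusted over the list alone, 3 rose and 5 fell in shPRMT5, 3 rose in shMEP50, and 3 rose and 4 fell in shpICln. The replicate block gave 9 rises and 4 falls in shMEP50, and 8 and 12 in shpICln. GNMT rose in shMEP50 by 0.73 on the log2 scale (edgeR adjusted p = 0.0387).

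Genes called in the same direction in all 3 lines numbered 3 rises and 1 fall, where independent lists of these sizes would give 0.0237 and 0.0418. All 3 lines share 1 estimate of the spread per gene, so their calls are not independent, and such reference counts can be too low. AZGP1, a secreted glycoprotein, rose by 1.2, 0.94 and 0.85 on the log2 scale in shPRMT5, shMEP50 and shpICln (edgeR adjusted p = 0.00428, 5e-04 and 0.00591). CITED2, a coactivator-binding protein, rose by 1.05, 0.55 and 1.04 (edgeR adjusted p = 0.0134, 0.0488 and 0.00527). The vesicle gene VAMP2 rose by 0.71, 0.61 and 0.64 (edgeR adjusted p = 0.0195, 0.00452 and 0.0166). KIF20B fell by 2.45, 1.5 and 1.27 (edgeR adjusted p = 0.00821, 0.00661 and 0.0425). This count of 4 was 0 without shPRMT5 replicate 2 without or with Dox, 1 without shPRMT5 replicate 3 without or with Dox, and 7 without shMEP50 replicate 2 with Dox. It was 1 without shpICln replicate 2 with or without Dox or replicate 3 without Dox, and 2 without each other shpICln library. In shPRMT5 and shMEP50, 22 genes rose in both and 54 fell in both, against 5.12 and 7.56 for independent lists. In shPRMT5 and shpICln, 17 rose and 9 fell in both, against 1.92 and 1.65, and in shMEP50 and shpICln 12 rose and 9 fell in both, against 1.33 and 3.26, and 2 went in opposite directions, against 4.32. In these lines 286 rose and 268 fell in both with the replicate block, against 138 and 152, and 367 went in opposite directions, against 291. Over all 23334 genes, log2 fold changes correlated at Pearson r = 0.06 (Spearman rho 0.09) between shPRMT5 and shMEP50, r = 0.31 (rho 0.38) between shPRMT5 and shpICln and r = 0.03 (rho 0.04) between shMEP50 and shpICln. The sign of the correlations with shMEP50 turned without its replicate 2 without Dox (r = -0.04 with shPRMT5 and -0.02 with shpICln) and without its replicate 3 with Dox (r = -0.03 and -0.06). In simulated data the changed genes were drawn separately for each line, and libraries had no structure by replicate, GC content or length. Such data gave r of -0.01, 0.01 and -0.01. These are correlations across genes, which are not independent replicates, and no library without Dox is shared between lines.

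The Dox effect itself was compared between lines by interaction contrasts. It differed for 375 genes between shPRMT5 and shMEP50 (267 with a higher and 108 with a lower log2 fold change in shPRMT5), for 32 between shPRMT5 and shpICln (23 and 9) and for 474 between shMEP50 and shpICln (193 and 281, and 1946 and 1746 with the replicate block). SNX12 fell in shMEP50 and differed from shPRMT5 by 2.09 (edgeR adjusted p = 1.65e-05) and from shpICln by -2.37 (edgeR adjusted p = 6.37e-07) on the log2 scale. PTPRR, a phosphatase gene, fell by 1.65 in shPRMT5 and rose by 0.91 in shMEP50 (difference -2.56, edgeR adjusted p = 0.000208), and CARMIL2 rose by 1.37 in shPRMT5 and fell by 0.83 in shMEP50 (difference 2.20, edgeR adjusted p = 0.000468). CGA, the glycoprotein hormone alpha subunit gene, had log2 fold changes of -1.87 in shPRMT5 and 2.98 in shpICln (difference -4.86, edgeR adjusted p = 0.0252). TAGLN2 rose by 0.79 in shPRMT5 and fell by 1.03 in shpICln (difference 1.82, edgeR adjusted p = 0.0252). Neuroendocrine markers had a median difference of 1.39 between shPRMT5 and shMEP50 (camera adjusted p = 6.55e-08, and adjusted p = 0.836 with an estimated correlation), and p53 targets of -0.62 (camera adjusted p = 4.01e-10, and adjusted p = 0.836 with an estimated correlation). Between shMEP50 and shpICln, histone methylation and Polycomb genes had a median difference of 0.21 (camera adjusted p = 0.179, and 0.0346 with the replicate block). With an estimated correlation it had adjusted p = 0.938, and 0.698 with the block.

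The counts of genes that differ moved with single libraries. For shPRMT5 against shMEP50 they were 40, 86, 122 and 87 without the shPRMT5 libraries (replicate 2 without and with Dox, replicate 3 without and with Dox). They were 686 and 143 without shMEP50 replicate 2 without and with Dox, and 162 and 875 without its replicate 3 without and with Dox. They were 210, 239 and 235 without shpICln replicate 2 with Dox, replicate 3 without Dox and replicate 3 with Dox. For shPRMT5 against shpICln they were 0 without shPRMT5 replicate 2 without Dox (edgeR, with 1317 at an unadjusted p under 0.05), 1 without each other shPRMT5 library, 78 without shMEP50 replicate 1 without Dox and 16 without its replicate 2 with Dox. Without shpICln libraries the same count was 1, 3, 16, 1, 3 and 11 (replicates 1, 2 and 3, each without and then with Dox). For shMEP50 against shpICln they were 273, 259 and 798 without shMEP50 replicate 2 with Dox, replicate 3 without Dox and replicate 3 with Dox. They were 305, 260, 219, 198, 288 and 263 without shpICln replicates 1, 2 and 3, each without and then with Dox. Of the 5 genes named per difference, all 5 stayed called in every such fit for shPRMT5 against shMEP50 and for shMEP50 against shpICln, and 0 of 5 for shPRMT5 against shpICln.

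Genes that fell in shMEP50 or shpICln often held a line-specific short sequence in the 3' UTR. The sequence was found by a search of all 7-base words in 12063 genes, made after the fold changes were known. In shMEP50, 268 of 486 fallen genes (55.1%) held ACTCTGT or CTCTGTA, 7-base parts of ACTCTGTA, against 13.7% of risen genes and 25.6% of genes not called. In shpICln, 66 of 109 fallen genes (60.6%) held GCTGGAC or CTGGACA, parts of GCTGGACA, against 14.9% and 20%. The words were picked by these same fold changes, so such contrasts are partly built in. In shPRMT5 the same search led to TGATGCCA, with 7-base parts in 27.9% of fallen, 10.8% of risen and 17.3% of genes not called. With the search run on a random part of the genes, its leading word had t of -13.6 (shMEP50), -6.6 (shpICln) and 0.5 (shPRMT5) in the other genes. Among named genes that fell in shMEP50, ANAPC13, SCG3, TRA2B, PSAT1, CA12, DNAJA1, BAG3, DIABLO and KIF20B held all 8 bases. SNX12, PON1, GPR85, EPB41L2, RAD51D, RAD51AP1, GINS1, BIRC5, PTBP1, HNRNPDL, ACLY, FADS1, MX1, GRWD1, NOP58, GCLM and PGD held 7. Among those that fell in shpICln, CS and ZIK1 held all 8 bases and DDR1, SLITRK5, GNG12 and TMX3 held 7. Named genes that rose held them too, SDK1 (8 bases), MFSD4A, SPATA18 and MSMO1 (7) in shMEP50, and SMOC1, CNKSR3, AZGP1 and ELF3 (7) in shpICln. The words of shMEP50 or shpICln were held by 5648 of 23334 genes (24.2%). Without these genes edgeR called 400 genes in shMEP50, 63 in shpICln and 434 in shPRMT5, against 878, 237 and 714 with them. Removing this share of genes can lower the counts by itself, whatever the words do. The lists of splicing factors, cholesterol synthesis, ribosomal proteins and neuroendocrine markers in shMEP50 then had camera adjusted p-values of 0.131, 0.0759, 0.0507 and 0.166, and those of fatty acid synthesis and homologous recombination in shpICln 0.422 and 0.152. That of fatty acid synthesis in shPRMT5 was 0.329. Other lists then passed, with 7e-04 for apoptosis regulators and 0.021 for the unfolded protein response in shMEP50, 0.00928 for the PRMT5 complex, which holds the target of the hairpin, in shPRMT5 and 0.0148 for the integrated stress response in shpICln. After a correction of each library for GC content and length, also chosen after seeing the data, androgen-repressed and fatty acid synthesis genes in shPRMT5 had 0.0818 and 0.0786. Homologous recombination, fatty acid synthesis and neuroendocrine genes in shpICln then had 0.104, 0.0614 and 0.0614, while glycolysis and the unfolded protein response in shMEP50 passed with 0.0217 and 0.037.

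**Figure D3:**
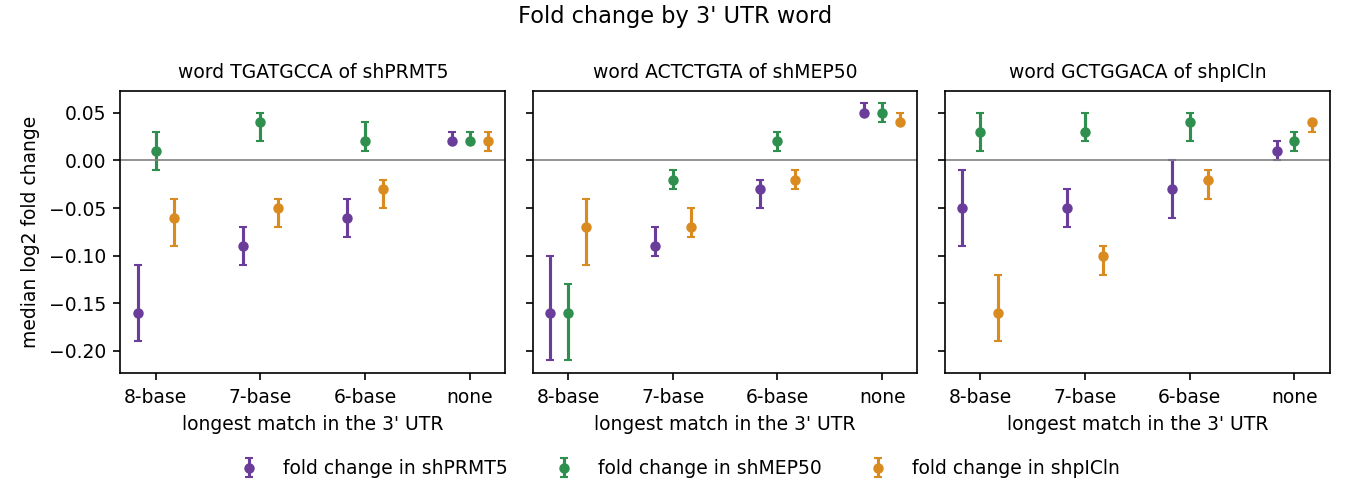
Median log2 fold change with Dox (vertical axis, with 95% bootstrap intervals over genes) of genes grouped by the longest part of the 8-base word in their 3' UTR (horizontal axis), for the leading word of each line in each panel and the fold change of each line in colour. Genes with all 8 bases of ACTCTGTA have a median of -0.16 in shMEP50 and those with none 0.05, but also -0.16 and 0.05 in shPRMT5, where no effect of the word was left after GC content, length and 3' UTR length were in the model (0.006, SE 0.0099). For GCTGGACA the medians are -0.16 and 0.04 in shpICln.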

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

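Of the tests weighed here, those of the GC and length trend itself, those of the 3' UTR words against GC content and length and in shPRMT5, that of the 7-base word in the targets, and the fit and the medians after correction for genes shared by shPRMT5 and shpICln were chosen only after the results were seen. The results listed here differed between lines in the test of the difference itself. This was the interaction contrast (edgeR) for genes and its camera form at the preset correlation for lists, and values are the first line minus the second on the log2 scale. The Dox effect differed for 375 genes between shPRMT5 and shMEP50, for 32 between shPRMT5 and shpICln and for 474 between shMEP50 and shpICln. Of 60 relabellings of Dox within both lines, drawn from 200, 3 gave at least 474 genes, the real one included, so chance is not excluded. The other 2 gave 2042 and 2573 genes, the highest other count. Both kept the libraries of replicate 1 of each line on the same side. Other relabellings did so too and gave 0 genes, so this trait alone does not account for the high counts. Among the 14 relabellings that part all pairs the highest other count was 130, and with the replicate block the real count was 3692. Of the 10 splits of the shMEP50 libraries 1, the real one, gave its 878 genes, and the highest other gave 21. Of the 10 splits of the shpICln libraries 1, the real one, gave its 237, and the highest other gave 0 (edgeR, with 207 to 1786 genes at an unadjusted p under 0.05, and no other tool run). With 10 splits a share under 0.05 is out of reach.

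Between shPRMT5 and shMEP50 the log2 fold change differed by 2.09 for SNX12, 2.04 for AC097460.1 and 2.11 for H2AFZ, which overlap, -2.56 for PTPRR and 2.20 for CARMIL2. The targets differed by -2.48 (PRMT5) and 1.86 (WDR77). Among genes named for shPRMT5, CX3CL1 differed by 3.78, SPOCK2 by 2.21, ICAM5 by 2.05, TPPP3 by 1.72, ETV4 by 1.88, ZBTB7C by -4.31, IL1RAP by -1.71, DDC by -2.01, RMI1 by -0.97, RRM2B by -1.66 and ENO2 by 1.69. Among those named for shMEP50, CYP3A43 differed by -2.75, S100P by -2.17, FCGRT by 3.36, SCG3 by 3.3, ANAPC13 by 2.36, PON1 by 3.20, GPR85 by 2.98, MAD2L2 by 1, FANCA by 0.91, BTG2 by -1.67, SPATA18 by -1.76, SNRPD2 by 1.82, PTBP1 by 0.71, ACLY by 1.69, MX1 by 1.54, GRWD1 by 0.78 and DIABLO by 0.98. Median differences of lists were 0.40 for DNA replication and S phase, -0.62 for p53 targets, 0.43 for mitochondrially encoded proteins, 0.23 for nuclear oxidative phosphorylation, 1.39 for neuroendocrine markers and -0.25 for histone methylation and Polycomb genes. None of these lists passed with an estimated correlation (camera adjusted p of 0.836 to 0.938).

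Between shPRMT5 and shpICln, DDR1 differed by 2.18, TAGLN2 by 1.82, CNKSR3 by -2, CGA by -4.86, PRMT5 by -2.75, CX3CL1 by 2.77, AKR1C3 by 2.55 and TAGLN by -1.32. Median differences of lists were -0.24 for homologous recombination, -0.28 for DNA replication and S phase, -0.55 for G2/M and mitosis, -0.14 for p53 targets, -0.15 for splicing factors, 0.44 for mitochondrially encoded proteins, -0.32 for ribosomal proteins, -0.15 for ribosome biogenesis and MYC targets, -0.31 for replication-dependent histones and 0.57 for neuroendocrine markers. With an estimated correlation none of these lists passed (camera adjusted p of 0.836 to 0.915).

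Between shMEP50 and shpICln, SNX12 differed by -2.37, AC097460.1 by -2.04, H2AFZ by -2.01, SARAF by -1.66, ANAPC13 by -2.59, WDR77 by -1.47 and CLNS1A by 1.38. Among genes named for shMEP50, FAIM2 differed by 3.09, PAPSS2 by 1.87, CYP3A43 by 3.24, S100A6 by 2.03, FCGRT by -2.37, EPB41L2 by -1.61, SNTB1 by -2.58, GNMT by 1.08, RAD51D by -0.91, MAD2L2 by -1.04, FANCG by -0.86, FANCA by -0.91, GINS1 by -1.44, RFC3 by -1.31, E2F1 by -1.46, TYMS by -0.86, BIRC5 by -0.90, BTG2 by 1.67 and SPATA18 by 1.29. SNRPD2 differed by -1.63, PTBP1 by -0.85, HNRNPDL by -0.94, PSAT1 by -1.19, ACLY by -1.51, CA12 by -1.82, GRWD1 by -0.71, HIST1H2AG by -1.53, TSPAN1 by 1.30, KRT14 by -2.71, CASP8 by 1.37, DIABLO by -0.87, GCLM by -1.07 and AKR1C3 by 2.11. Among those named for shpICln, PDK4 differed by -3.71, PTK6 by -1.93, MAPK4 by -2.56, TAGLN by -1.33, DDR1 by 1.96, GPRIN2 by 1.52, CS by 1.34, GNG12 by 1.2, CPNE1 by 0.95 and HNRNPA1 by -0.83. Median differences of lists were -0.32 for homologous recombination, -0.29 for the Fanconi anaemia pathway, -0.62 for DNA replication and S phase, -0.38 for G2/M and mitosis, 0.43 for p53 targets, -0.30 for Sm proteins and the SMN complex, -0.19 for splicing factors, -0.18 for nuclear oxidative phosphorylation, 0.28 for cholesterol synthesis, -0.21 for glycolysis and hypoxia, -0.44 for ribosomal proteins, -0.18 for ribosome biogenesis and MYC targets, and -0.84 for neuroendocrine markers. With an estimated correlation, 0 of the 108 list differences passed (camera, 5 at an unadjusted p under 0.05), against 29 at the preset one.

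Across genes, log2 fold changes correlated with GC content at r = 0.32 in shPRMT5, 0.22 in shpICln and 0.07 in shMEP50, and with length at -0.27, -0.33 and 0.01. After a correction of each library for both, 407 of 714 genes (57%) stayed called in the same direction in shPRMT5, where edgeR called 661 in all. In shpICln with the replicate block, 2574 of 3646 (70.6%) did. This argues against a smooth trend with GC content and length as the whole of the changes. Library bias of other kinds was not tested. The calls that ended did so at smaller fold changes, with signed medians of 0.89 before and 0.69 after (median SE 0.197 and 0.218) for 307 genes in shPRMT5, and 0.36 and 0.23 (0.0955 and 0.0893) for 1072 in shpICln. In the 3 pairs of shpICln the GC slope changed with Dox by 0.105, -0.0183 and 0.0646 (mean 0.0508, log2 scale per 10 points of GC) and the length slope by -0.107, -0.0756 and -0.0921 per doubling of length. In shPRMT5 the GC slope changed by 0.146 against ranges of 0.0187 and 0.0182 within its groups of 2, and in both lines a response to the knockdown and a difference in library making cannot be told apart, since the labels give no batch.

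With GC content, length and 3' UTR length in the model, genes holding 7 or 8 bases of ACTCTGTA had an effect of -0.157 (SE 0.0082, log2 scale) in shMEP50 relative to genes without them, at medians of -0.16 (8 bases), -0.02 (7) and 0.05 (none), and parts of GCTGGACA one of -0.1 (SE 0.0069) in shpICln (-0.16, -0.1 and 0.04). The leading words had t of -18.3 and -12.5 in such models against at most 5.1 and 5.0 in 100 permutations, which argues against these properties as the cause. The effect of the shMEP50 word in shPRMT5 was 0.006 (SE 0.0099), which argues against loss of PRMT5, the partner of MEP50, as its source. Loss of MEP50 by itself stays open, since WDR77 was not called in shPRMT5 and no protein was measured here. A candidate explanation is that the guide strand of each hairpin acts on transcripts with a matching site, since 9 of 12 CLNS1A transcripts hold GCTGGAC and GCTGGACA (position 770 of ENST00000525428, coding) and 4 of 4 WDR77 transcripts hold ACTCTGT (position 746 of ENST00000235090, coding), although 35.7% and 29% of genes hold these 7 bases by themselves. The 7 bases are not particular to the target of their own line, since 3 of 4 WDR77 transcripts hold GCTGGAC and 2 of 12 CLNS1A transcripts hold ACTCTGT. For shMEP50 the test fixed before the result asked for all 8 bases, which 0 of 4 WDR77 transcripts hold, so that prediction failed. Genes with the first 7 but not all 8 had an effect of -0.104 (SE 0.0097, median -0.01) relative to genes without the word. Those with the last 7 had a larger one (-0.144, SE 0.0106, median -0.04), and 0 of 4 WDR77 transcripts hold the leading CTCTGTA. The word was picked by these same fold changes, so these effects cannot decide whether 7 bases are enough. A 7-base guide site therefore stays open. In shPRMT5 the leading word GATGCCA had t of -5.1 against at most 5.1 permuted and 0 of 28 PRMT5 transcripts hold it or TGATGCC, so none holds any 7 bases of TGATGCCA, which argues against a guide site of that word, and the hairpin sequences were not analysed here. Of the words with the highest t, CTCAAAA in shPRMT5 (6.1) and ACAGGCG in shpICln (5.8) also lay beyond the permuted range. AATTTTT in shMEP50 (4.1) did not.

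In both shPRMT5 and shpICln 17 genes rose and 9 fell, among them LDHB (0.65 and 0.72), NRIP1 (-0.94 and -1.02) and TP53I11 (-1.23 and -0.72), named after their values were seen. Signed by direction, their median log2 fold changes were 0.79, 0.71 and, in shMEP50, 0.13 (95% interval 0.05 to 0.27). The last lies below 0.36, a bound whose rule was fixed before the result, which argues against doxycycline itself as the main source for the set. A smaller effect of doxycycline stays open, since the median in shMEP50 lies above 0. The intervals here come from resampling the 26 genes, which are not independent, so they do not measure the spread between libraries. The genes were also picked by their calls in shPRMT5 and shpICln, which can raise the medians there. The sign was shared in shMEP50 by 19 of 26 genes and 4 were called there too, so doxycycline stays open for those 4. After the correction for GC content and length 13 of 26 (50%) stayed called in both lines, and the medians of all 26 were smaller but far from 0, at 0.6 (95% interval 0.49 to 0.69) and 0.63 (0.53 to 0.76), and r between the lines over all genes was 0.29 against 0.31, which argues against that trend as the whole of them. A response shared by loss of PRMT5 and pICln may account for these genes and was not tested, since a non-targeting hairpin with Dox was not analysed here.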

How the results depend on the processing

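Fits that leave out genes with the 3' UTR words, correct for GC content and length or use the most-counted transcript were chosen only after the results were seen. Counts of called genes are given in the order shPRMT5, shMEP50, shpICln, shPRMT5 against shMEP50, shPRMT5 against shpICln, shMEP50 against shpICln and all 3 lines, where edgeR gave 714, 878, 237, 375, 32, 474 and 4. DESeq2 gave 2339, 1734, 1053, 1394 (817 higher and 577 lower in shPRMT5, against 267 and 108), 403, 1341 and 38. The replicate block gave 5711, 3721, 3646, 4139 (2044 higher and 2095 lower), 1463, 3692 and 314. It gave 479 shared rises and 496 shared falls in shPRMT5 and shMEP50 (228 and 227 for independent lists), and 721 and 926 in shPRMT5 and shpICln (215 and 231). In shPRMT5 the libraries share only a number (r = -0.02 for both pairs, and 0.02 with the other number), and the block there is no paired result. With 2 libraries per group the deviations mirror each other, so these values are 1 measurement. Beside the calls named in the report it ended no list call and no call of a named gene in any line. A test against a fold of 1.5 gave 11, 73, 1, 40, 1, 31 and 0, and transcripts without summing gave 5910, 4831, 1715, 2211, 332, 3140 and 31. Without genes holding the words the counts were 434, 400, 63, 134, 4, 174 and 1, with fewer genes tested. The GC and length correction gave 1420 in shMEP50, 445 in shpICln, 66 and 848 for the differences of shpICln from shPRMT5 and shMEP50, and 9 in all 3 lines. With the replicate block it gave 5158, 4118, 3278, 3877, 1613, 3704 and 268, and 25 of the 26 genes shared by shPRMT5 and shpICln stayed called. Each line fitted alone gave 5290 in shPRMT5, 48 in shMEP50 and 0 in all 3 lines, and can give no difference between lines. For shPRMT5 against shpICln limma-voom gave 50 and a filter of at least 1 CPM in at least 8 libraries 49, and limma-voom gave 2 in all 3 lines. The counts of 0 are from edgeR, and the other tools gave 38 and 2 in all 3 lines. Counts not printed for a setting stayed within 1.5 times, and no filter on low counts removed nothing, so it tests nothing. Leaving out each library gave ranges of 0 to 1216, 628 to 928, 26 to 374, 40 to 875, 0 to 78, 198 to 798 and 0 to 7, where a lone library is assumed to vary like the other groups. The 0 for shPRMT5 (edgeR) had 2687 genes at an unadjusted p under 0.05 and that for shPRMT5 against shpICln 1317. Of the 176 called values of named genes, 87 were called with each line alone (of 161 tested there), 35 at a fold of 1.5, 84 without genes holding the words (of 101), and 99 to 166 without single libraries. All 3 targets were called, 2 to 3 without single libraries, and all but CLNS1A with each line alone and at a fold of 1.5. Correlations of effects ranged from -0.04 to 0.14, 0.24 to 0.35 and -0.06 to 0.09 without single libraries, and that of shPRMT5 with shpICln was 0.46 with the CPM filter. Of 108 list tests, camera called 28 at the preset correlation and 0 with an estimated one (10 at an unadjusted p under 0.05), and fry called 12. The fry calls include mismatch and base excision repair in shMEP50 and shpICln (fry adjusted p = 0.00625 and 0.0197) and apoptosis regulators in shMEP50 (0.0335). Camera did not call these at the preset correlation (adjusted p = 0.0914, 0.152 and 0.102). The test of ribosomal proteins in shMEP50 turned downward without replicate 1 without Dox (camera adjusted p = 0.712) and without replicate 3 with Dox (0.656), in a range from 3.13e-08 over single libraries left out. Over all settings, values of named genes kept their direction and side of the threshold in 4561 cases, lost the call in 909 and gained it in 19, and those of lists in 2232, 81 and 61. Except for fewer genes or libraries, the cause was not tested.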

Other observations

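The sets of genes described here were chosen only after the results were seen. In shPRMT5 and shMEP50 alike, 54 genes fell, of which 11 are in the lists of S phase or mitosis fixed before the data were examined. The kinetochore genes NDC80 (log2 fold changes of -0.98 and -1.02 in shPRMT5 and shMEP50) and SPC25 (-1.18 and -1.06), the chromosomal passenger genes INCENP (-1.19 and -1.03) and CDCA8 (-0.74 and -0.73), and the spindle genes TACC3 (-0.66 and -0.57) and SPAG5 (-0.72 and -0.78) fell in both. So did the cell cycle transcription factor gene MYBL2 (-0.80 and -1.21), the replication kinase gene CDC7 (-0.96 and -0.79), the nuclear lamina gene LMNB1 (-0.80 and -0.79) and the protease gene TMPRSS11E (-2.95 and -2.65). Among the 22 genes that rose in both were the aldehyde dehydrogenase gene ALDH3A1 (2.17 and 1.71), the mitophagy kinase gene PINK1 (0.94 and 0.71), the adhesion gene BCAM (1.37 and 1.07) and MISP (1.87 and 1.73). Over the same lines 18 genes were called in opposite directions, against 14.2 for independent lists.

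In the authors' deposited table, 20160 transcripts were higher and 21911 lower with Dox at an adjusted p under 0.05 in shPRMT5 (of 127454 tested), 11317 and 14211 in shMEP50 (of 128895), and 17344 and 18019 in shpICln (of 131275). The edgeR fit of transcripts without summing called 5910, 4831 and 1715. The authors' table thus has more calls in shpICln than in shMEP50, the reverse of the order found here. The cause was not tested. Libraries of shMEP50 and shpICln with the same replicate number had deviations from their group means that correlated at r of 0.06 to 0.56 (median 0.3, 12 pairs), and those with different numbers at -0.43 to 0.18 (median -0.19, 24 pairs). Deviations cancel out within a group, so positive values for the same number bring negative ones for different numbers.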
